A study of Mus musculus with 12 samples.

How the data were processed

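RNA from the livers of 3-month-old mice was measured on Affymetrix GeneChip mouse arrays, which carry short probes grouped into probe sets. Per the labels, the 12 arrays fall into 3 groups of 4: wild type, Atp7b-/- and Atp7b-/- with zinc. The labels state that supplemental zinc was given to 4 mutant mice. The dose, its duration and the sex of the mice are not given in the sources used here, and neither is whether every array of the other groups came from a separate animal. The p-values therefore measure the spread between arrays, part of which may be technical.

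The deposited values are on a log2 scale, normalized between arrays by the authors with a method that is not stated. They ran from 2.22 to 15.2, with array medians between 5.63 and 5.71, and were used without further scaling. No value was missing, and no pair of arrays held identical values. The number of arrays limits the precision of every value given.

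The table holds 45101 probe sets. The 64 control probe sets were left out of the tests. Of the rest, 34945 are listed with exactly 1 gene symbol, 932 with several and 9160 with none, and only the first kind was used for genes. Where a gene had more than 1 probe set, as 9010 genes did, the probe set with the highest mean over all 12 arrays stood for it, which gave 18193 genes. Gene symbols were updated and places taken from the RefSeq annotation of the mouse genome build GRCm38.

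The groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit of group means over all 12 arrays (lmFit, contrasts.fit and eBayes). The 3 comparisons were Atp7b-/- against wild type, zinc-treated against untreated Atp7b-/-, and zinc-treated Atp7b-/- against wild type. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, whatever the size of the change. Errors given after ± are SDs between the 4 arrays of a group. All adjusted p-values of genes come from limma.

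The 41 gene lists, covering pathways and the cell types a liver sample could hold, were tested with limma's camera at a preset inter-gene correlation of 0.01, again at an adjusted p under 0.05. Camera asks whether the genes of a list moved one way more than other genes did. Beside it stand camera with a correlation estimated from the data and fry, which asks whether the genes of a list moved, on balance, one way. For each list the number of changed members is given over all genes tested and adjusted over the list alone.

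Genes were named by a fixed rule: up to 12 with the largest rise and 12 with the largest fall per comparison among called genes whose arrays did not overlap, whose higher group mean lay above the median of all genes and of that group, and whose symbol was not a clone or predicted name. The rule adds up to 4 members of each list with the smallest adjusted p, the 10 genes with the largest opposite changes with zinc, and Atp7b, Mt1 and Mt2. The text uses a part of these genes, picked after their values were seen. The lists, the tests of genes and lists, this rule and all but 2 of the alternatives given below were set before the data were examined. Part of the tests of possible causes were chosen after the results were seen, as stated with them. Mcph1 and Nek3 lie outside the rule and were chosen after their values were seen.

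Comparisons that share a group are correlated even without any effect, so their overlap was set beside 100 draws of simulated unchanged groups and beside the 6 ways of splitting the shared group between both comparisons. The fits were tested on simulated data with 200 changed genes among 18193. For the 3 comparisons in the order given above, 46, 47 and 47 of 50 genes changed by 1 log2 unit were recovered, and 30, 23 and 25 of 50 changed by 0.5. False calls numbered 16, 2 and 15. List tests were also run on 50 simulated draws without any effect. Camera at the preset correlation then called a median of 9, 10.5 and 10 lists and at most 18, 19 and 21. With an estimated correlation a list was called in 0, 0 and 1 of the draws, and with fry in 1, 0 and 1. The cell cycle list of 39 genes, shifted by 1 log2 unit, was called in 50 draws at the preset correlation and in 49 with the estimated one. No other gene changed in those draws, whereas in the data many did. In Atp7b-/- against wild type the same list had a mean change of 1.08. Camera with an estimated correlation gave it an adjusted p = 0.541, so the recovery in those draws does not carry over to these data.

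The alternatives covered other normalizations, other ways of choosing probe sets, other variance models, array weights, a minimum change of 1 log2 unit, the replicate number as a block, and leaving out each array in turn. After seeing the data, 2 more were added: the zinc-treated arrays that carry pancreatic transcripts left out, and those together with the Atp7b-/- array that correlated least with its group. A further set that left out 1 Atp7b-/- array and 1 wild type array was also run, and was dropped because nothing measured set that wild type array apart. Intervals of list medians come from 2000 bootstrap draws over the genes of a list. Figures were drawn with matplotlib 3.10.9.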

Results

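Gene expression was measured in 12 liver samples of mice aged 3 months: 4 from wild type, 4 from Atp7b-/- and 4 from Atp7b-/- mice given zinc, all labelled as C57Bl/6. Atp7b is the copper-transporting ATPase through which hepatocytes pass copper into bile, and its loss causes Wilson disease in humans. Levels are log2 intensities for 18193 genes, each read from 1 probe set. The first principal component, with 48.9% of the variance, ordered the groups as wild type, zinc-treated and untreated Atp7b-/-.

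**Figure D1:**
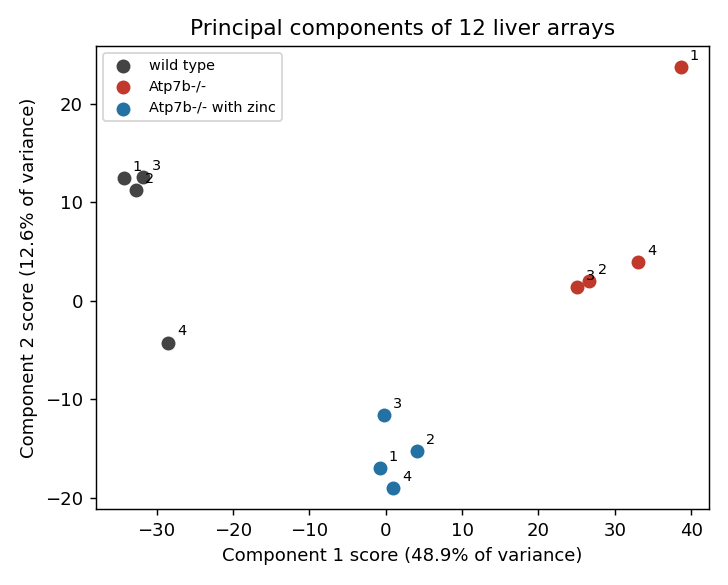
Scores of the 12 liver arrays on the first and second principal components, which hold 48.9% and 12.6% of the variance; each point is an array, labelled with its replicate number and coloured by group. Wild type arrays lie on the left, untreated Atp7b-/- arrays on the right and zinc-treated arrays between them on component 1.

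Of the 12 arrays, 3 stood apart. Replicate 1 of untreated Atp7b-/- had a median correlation of 0.991 with its group, against 0.996 for each of the other 3. Zinc-treated replicates 2 and 3 carried transcripts of pancreatic acinar cells, with list means 4.05 and 1.20 log2 units above the median array. They also differed from zinc-treated replicates 1 and 4 in other genes. Scores on the fourth principal component were 10.2 and 9.51 against -14.6 and -11.5. Means of fatty acid oxidation genes against wild type were -0.26 and -0.38 against 0.32 and 0.34. Leaving these arrays out therefore removes more than pancreatic transcripts. Every array had a male pattern, with Xist between 4.62 and 5.23 and a mean of the Y-linked genes between 7.94 and 8.59. The mean 3' to 5' difference of the actin and Gapdh control probe sets, a measure of RNA degradation, was larger in every untreated Atp7b-/- array than in any other array. In both comparisons that use untreated Atp7b-/- arrays, RNA quality therefore cannot be told apart from group.

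The targeted gene, Atp7b (gene 11979, chromosome 8, 21992783 to 22060074), was lower in every Atp7b-/- array than in every wild type array. Its log2 level was 8.51, 8.59, 8.61 and 8.69 in wild type, 7.17, 7.25, 7.11 and 6.91 in untreated Atp7b-/-, and 6.85, 6.92, 6.57 and 6.98 with zinc. The change against wild type was -1.49 without zinc (adjusted p = 2.04e-07) and -1.77 with it (adjusted p = 1.22e-07). Between treated and untreated mutants it was -0.28 (adjusted p = 0.114). The changes against wild type were -0.90 and -0.96 as the mean of all its probe sets. Where this probe set lies relative to the disrupted part of the gene is not given in the sources used here, and a probe set outside that part checks nothing.

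The comparison of Atp7b-/- with wild type asks what loss of the copper transporter changed in the liver. Of 4 metallothioneins, Mt1 and Mt2, which bind copper and zinc, rose, and the other 2 did not pass the test. Mt1 went from 9.03 ± 1.66 (SD, n = 4) to 14.7 ± 0.11 and Mt2 from 8.05 ± 1.06 to 13.8 ± 0.45. Mt1 was then close to the highest value of any probe set, so its differences from wild type are lower bounds. With them rose 16 of 18 targets of p53 and 19 of 39 cell cycle genes, of which 2 fell. Of male-biased liver genes 13 of 17 fell, of growth hormone and IGF genes 6 of 14, and of macrophage markers 10 of 25. None of these lists was called with an estimated correlation. Fry, which does not set a list against other genes, called all of them but the macrophages (adjusted p = 0.0783). Its adjusted p was 0.00163 for male-biased genes. For metallothioneins, p53 targets, the cell cycle and growth hormone and IGF genes it was 0.000249. In total 4480 of 18193 genes changed, 2608 up and 1872 down, and 655 of them by at least 1 log2 unit (551 up, 104 down). The share that was higher depended on the scaling: 58.2% as deposited, 49.6% after quantile normalization and 68.1% after median centring. In 3759 of the 4480, the arrays of the groups did not overlap. Over all genes 26.4% showed no overlap, where chance gives 2.86%.

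Of 18 measured p53 targets, 16 rose and 0 fell over all genes tested, and 16 rose adjusted over the list alone, with a median change of 1.81. They included the cell cycle inhibitor Cdkn1a (3.51), Ccng1 (2.59), Btg2 (2.36) and Ddit4l (1.80). The list had an adjusted p = 0.541 with an estimated correlation. Of 39 cell cycle genes, 19 rose and 2 fell (21 and 3 adjusted over the list alone), with a median of 0.89 and an adjusted p = 0.541 with an estimated correlation. Birc5, an inhibitor of apoptosis needed for cell division, rose by 4.60, and the mitotic regulators Cdc20, Cdk1 and Ube2c by 3.95, 3.40 and 3.29. Without replicate 1 of Atp7b-/-, where the cell cycle mean was highest, the median of this list was 0.49. Outside the lists, the cohesion factor Esco2 rose by 5.97 (3.71 ± 0.24 to 9.68 ± 0.86; adjusted p = 5.22e-08), the spindle checkpoint kinase Ttk by 4.36, the kinetochore gene Zwilch by 4.62 and Shcbp1 by 4.98. Ttk rose by 2.73 as the mean of its probe sets. Esco2 in wild type was below the lower quartile of the arrays (4.13 to 4.29), and differences from a level that dim are taken as lower bounds.

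Of 16 immediate early genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.18 and an adjusted p = 0.542 with an estimated correlation. Egr1 rose by 3.91 and Jun by 1.93, both encoding transcription factors, and Zfp36, which promotes mRNA decay, by 1.97. Of 24 NRF2 targets, the genes of the oxidative stress response, 10 rose and 3 fell (12 and 3 adjusted over the list alone; adjusted p = 0.541 with an estimated correlation). Among them were Srxn1 (1.35), Gstm4 (1.24), Ugdh (1.03) and Ephx1 (1.01). Of 19 fetal liver and tumour markers, 9 rose and 0 fell, by either count. Alpha-fetoprotein, Afp, rose by 3.28, the trefoil factor Tff3 by 2.61 and Anxa5 by 1.17. The median of this list was 0.64, and 0.10 without replicate 1 of Atp7b-/-, and the list had an adjusted p = 0.711 with an estimated correlation. With the mean of all probe sets of a gene Afp rose by 1.47 and Srxn1 by 0.77, and without probe sets prone to cross-hybridise Srxn1 rose by 0.87.

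Of 17 male-biased liver genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.73 and an adjusted p = 0.541 with an estimated correlation. Moxd1 went from 11.3 ± 1.00 to 4.70 ± 0.36 and Ugt2b38, a glucuronosyltransferase, from 9.67 ± 0.60 to 3.83 ± 0.33, a dim level, so that its difference is a lower bound. The organic anion transporter Slco1a1 fell by 1.84 and the steroid dehydrogenase Hsd3b5 by 1.85. Of 14 genes of growth hormone and IGF signalling, 6 fell and 0 rose, by either count, with a median of -0.19 and an adjusted p = 0.541 with an estimated correlation. Igf1 fell by 0.56 and Igfals, its carrier in blood, by 0.72. Socs2 fell by 1.53 too, but its call was lost in 15 of the settings tried, median centring among them. Outside the lists, the receptor Egfr fell by 2.90 and Dio1, which activates thyroid hormone, by 2.55. As the mean of all probe sets of the gene, the change was -1.22 for Egfr and -0.52 for Socs2.

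Of 25 macrophage markers, 10 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.51 and an adjusted p = 0.749 with an estimated correlation. Adgre1 fell by 0.71 and Csf1r by 0.71, although Csf1r lost its call without replicate 4 of Atp7b-/-, at -0.62. The median was -0.79 without replicate 1 of Atp7b-/-, whose mean lay within the wild type range. Of 20 lymphocyte markers, 2 fell over all genes and 0 adjusted over the list alone (adjusted p = 0.749 with an estimated correlation). Without replicate 1 of Atp7b-/- 6 of them fell, and the median was -0.27 in place of -0.16. Of 25 genes of the urea cycle and amino acid breakdown, 8 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 0.663 with an estimated correlation), among them Agxt2 (0.89) and Kmo (0.57). Of 38 genes of oxidative phosphorylation 6 rose and 0 fell, by either count, with a median of 0.08 (adjusted p = 0.730 with an estimated correlation).

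Of 26 interferon response genes, 9 fell and 5 rose (11 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.225). Irf7 fell by 0.88 and Ifit2 by 0.78. Without replicate 1 of Atp7b-/- 13 fell, and the preset test of the list gave an adjusted p = 0.0144, where the largest over the settings tried was 0.547.

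Metal handling genes moved both ways. Of 20 copper handling genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone), and the list was not called. The prion protein gene Prnp, which binds copper, rose by 0.73, and Slc31a1, the main copper importer, and Sco2, a copper chaperone of cytochrome oxidase, fell by 0.35 and 0.49. Of 19 iron handling genes, 6 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.599 with an estimated correlation). The iron exporter Slc40a1 fell by 0.75 and Hfe rose by 0.42. Hamp2 rose by 1.63 on a probe set that can also bind related transcripts, and its change was -0.13 without probe sets of that kind.

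**Figure D2:**
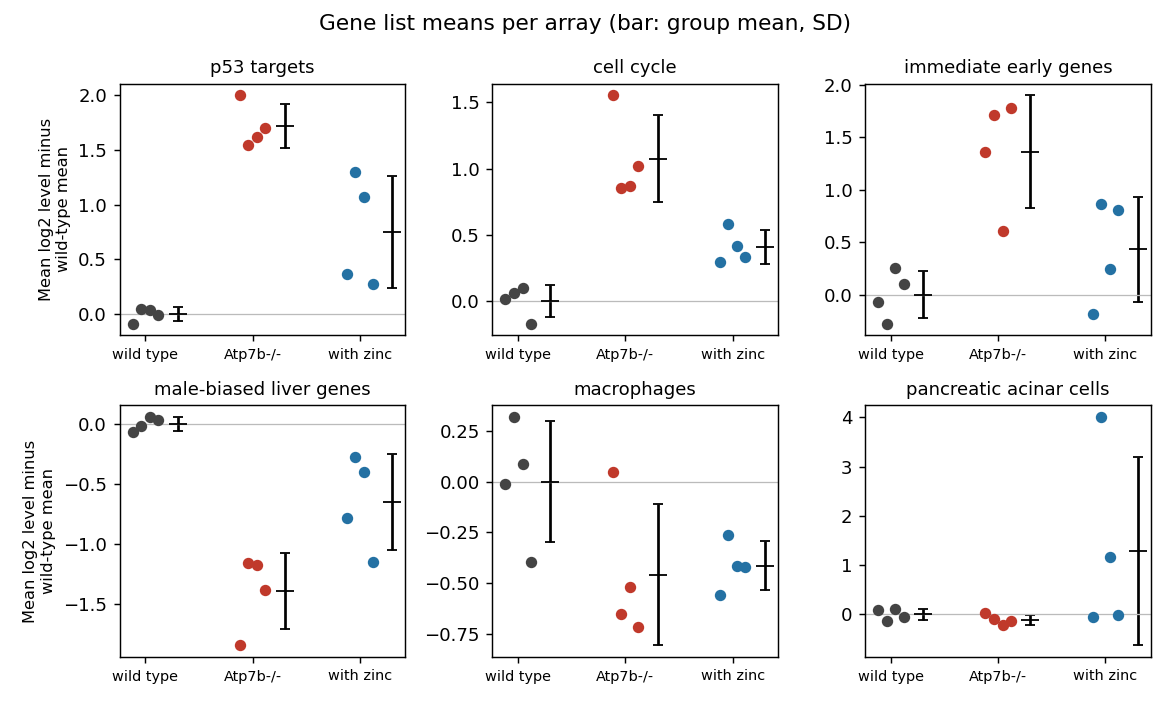
Mean log2 level of 6 gene lists in each of the 12 arrays, as the difference from the wild type mean; points are arrays and the bar beside each group is its mean with its SD. The p53 targets lie between 1.54 and 2.00 in the untreated Atp7b-/- arrays and between 0.27 and 1.30 with zinc, and pancreatic acinar transcripts reach 4.01 and 1.17 in 2 of the zinc-treated arrays.

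By camera at the preset correlation, 13 of 41 lists were called, 9 up and 4 down. That test called a median of 9 lists in simulated data without an effect, and with an estimated correlation it called 0 of the 41 here (smallest unadjusted p = 0.0274), while fry called 12. List medians depended on the setting: 1.14 for p53 targets with the mean of all probe sets, 0.54 for the cell cycle without probe sets prone to cross-hybridise, 0.19 for fetal markers with array weights, and 0.04 for oxidative phosphorylation after quantile normalization. With dim genes left out they were 1.93 for immediate early genes, 1.13 for fetal markers, -0.48 for lymphocytes and -0.29 for growth hormone and IGF genes, which had -0.34 with the mean of all probe sets and -0.30 without replicate 3 of Atp7b-/-. The lists of metallothioneins, lymphocytes, iron handling, oxidative phosphorylation and growth hormone and IGF signalling each had an adjusted p = 0.0493 at the preset correlation. Only 8 lists were called without replicate 2 of Atp7b-/- or without replicate 1 of the zinc-treated group, which shares the estimate of the spread.

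The comparison of zinc-treated with untreated Atp7b-/- mice asks which genes differed with zinc. Of 39 cell cycle genes 17 were lower with zinc, and of 18 p53 targets 12, although neither list was called with an estimated correlation. Fry gave each of these lists an adjusted p = 0.0215. Some genes that had fallen in the mutant were higher. Ugt2b38 went from 3.83 ± 0.33 to 9.61 ± 0.98, Egfr from 9.60 ± 0.45 to 11.7 ± 0.50 and Dio1 from 8.30 ± 0.19 to 10.3 ± 0.49. As the mean of its probe sets Egfr rose by 0.72. Mt1 and Mt2 differed by -0.26 (adjusted p = 0.840) and -0.17 (adjusted p = 0.856). Mt1, at 14.7 in untreated mutants, was close to the highest value of any probe set, so a further rise could hardly show. In total 1190 genes changed, 309 up and 881 down, so 26.0% were higher, and 205 changed by at least 1 log2 unit (38 up, 167 down). After quantile normalization 40.0% of the called genes were higher.

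Of 39 cell cycle genes, 17 fell and 0 rose with zinc (20 and 0 adjusted over the list alone), with a median of -0.47 and an adjusted p = 0.449 with an estimated correlation. Birc5 fell by 3.57, the mitotic kinases Bub1 and Cdk1 by 2.85 and 1.73, and Ube2c by 1.59. Esco2 fell by 3.14 and Ttk by 2.96. Bub1 fell by 1.46 and Ttk by 1.88 as the mean of their probe sets, and Bub1 was dim with zinc (3.86), so its fall is a lower bound. Of 18 p53 targets, 12 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.92 and an adjusted p = 0.449 with an estimated correlation. Cdkn1a fell by 1.92, Btg2 by 1.47, Ddit4l by 1.34 and Ccng1 by 1.32. The p53 list means were 1.30 and 1.07 in zinc-treated replicates 2 and 3, which carried pancreatic transcripts, and 0.36 and 0.27 in the other 2. Of 16 immediate early genes, 4 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.533 with an estimated correlation). Jun fell by 2.29 and Zfp36 by 1.45. With fewer arrays, those carrying pancreatic transcripts left out, their changes were -2.49 and -1.36 and no longer passed. Zfp36 also lost its call without replicate 4 of Atp7b-/-, at -1.32.

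Genes of other functions with large falls were the axon guidance receptor Robo1 (-4.07), the drug exporter Abcb1b (-3.30), Stap1 (-3.47), Cfap53 (-3.21) and Slc35f2 (-2.97). With the mean of all probe sets of a gene the changes were -1.48 for Robo1, -1.77 for Abcb1b and -1.49 for Slc35f2. Obp2a fell by 4.37, and its change was -4.44 with those fewer arrays, where it no longer passed. Of 19 fetal liver and tumour markers, 3 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.650 with an estimated correlation). Afp fell by 1.57 (-0.69 as the mean of its probe sets) and Anxa5 by 0.64. Without replicate 1 of Atp7b-/- the preset test of that list gave an adjusted p = 0.230. Of 25 genes of the urea cycle and amino acid breakdown, 4 fell and 0 rose (6 and 1 adjusted over the list alone; adjusted p = 0.546 with an estimated correlation), Kmo by 0.46 among them. Of 38 genes of oxidative phosphorylation 2 fell and 0 rose, by either count (adjusted p = 0.538 with an estimated correlation). Of 19 iron handling genes 2 fell and 1 rose, by either count (adjusted p = 0.533 with an estimated correlation). Without the arrays carrying pancreatic transcripts their preset tests gave adjusted p = 0.0924 and 0.315, at medians of -0.046 and -0.12 in place of -0.056 and -0.17.

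Of 16 genes of bile acid synthesis, 4 rose and 0 fell with zinc (7 and 0 adjusted over the list alone), with a median of 0.18 and an adjusted p = 0.449 with an estimated correlation. The very long chain acyl-CoA synthetase Slc27a2 rose by 0.43. The 7-hydroxylase of oxysterols Cyp39a1, already 0.78 above wild type in untreated mutants, rose by a further 0.64. The racemase Amacr, which had fallen by 0.42 in untreated mutants, rose by 0.37. Cyp39a1 lost its call at 0.59 and 0.54 without zinc-treated replicates 1 and 4, and Amacr at 0.33 without the arrays carrying pancreatic transcripts. Of 17 male-biased liver genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.629 with an estimated correlation). Without the arrays carrying pancreatic transcripts, 1 rose and 1 fell, and the preset test of the list gave an adjusted p = 0.423. Of 14 growth hormone and IGF genes, 3 rose and 0 fell, by either count (adjusted p = 0.449 with an estimated correlation). The binding protein Igfbp2 rose by 1.11. Socs2 rose by 1.97 and Stat5b by 0.28, calls lost in 9 and 18 of the settings tried. Igf1 and Igfals, which had fallen in untreated mutants, differed by 0.19 and -0.02 and did not pass. Hsd17b6, a steroid dehydrogenase, rose by 1.92, and by 0.95 as the mean of its probe sets. Of 21 genes of cholesterol biosynthesis 1 rose and 0 fell, by either count (adjusted p = 0.728 with an estimated correlation), and without replicate 1 of Atp7b-/- the preset test gave an adjusted p = 0.416.

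Among cell type lists, 5 of 29 genes of extracellular matrix and stellate cells rose and 0 fell, by either count, with a median of 0.17 and an adjusted p = 0.449 with an estimated correlation. Reln rose by 0.61, and by 0.39 as the mean of its probe sets. Without the arrays carrying pancreatic transcripts 1 gene of this list rose. Of 18 endothelial genes, Clec4g rose by 0.43 and Tek fell by 1.06, while 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.449 with an estimated correlation). Without the arrays carrying pancreatic transcripts the change of Tek was -1.10 and no longer passed. That of Clec4g lost its call at 0.44 without those and replicate 1 of Atp7b-/-, and at 0.27 as the mean of its probe sets. Of 12 pancreatic acinar genes 0 passed the test, at a median change of 1.40 that came from zinc-treated replicates 2 and 3 (adjusted p = 0.650 with an estimated correlation). The protease genes Cpb1 and Prss2 differed by 2.54 (adjusted p = 0.152) and 1.37 (adjusted p = 0.219). Of 8 adipocyte genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.449 with an estimated correlation), and their mean was highest in zinc-treated replicate 2.

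By camera at the preset correlation 15 lists were called, 8 up and 7 down, against 0 with an estimated correlation (smallest unadjusted p = 0.0121) and 7 by fry, where simulated data without an effect gave a median of 10.5 at the preset correlation. The median was 0.10 for matrix and stellate genes without zinc-treated replicate 4, and 0.10 for bile acid synthesis without the 3 arrays that stood apart. Without the 2 zinc-treated arrays carrying pancreatic transcripts 614 genes were called, 526 of them among the 1190, and without replicate 4 of Atp7b-/- the count was 689.

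The comparison of zinc-treated Atp7b-/- mice with wild type asks which differences remained with zinc. Of 4 metallothioneins 2 were higher, by either count, Mt1 at 14.4 ± 0.15 and Mt2 at 13.6 ± 0.48, which is 5.37 and 5.55 above wild type. Also higher were 8 of 24 NRF2 targets and 11 of 39 cell cycle genes, and 8 of 26 interferon response genes were lower. None of these lists was called with an estimated correlation. By fry the adjusted p was 0.000934 for metallothioneins and 0.00410 for NRF2 targets. It was 0.0680 for the cell cycle and 0.341 for interferon response genes, which fry did not call. In total 1386 genes changed, 890 up and 496 down, and 229 of them by at least 1 log2 unit (195 up, 34 down). The arrays of the groups did not overlap in 1264 of the 1386, and in 14.3% of all genes, where chance gives 2.86%.

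Of 39 cell cycle genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.17 and an adjusted p = 0.868 with an estimated correlation. Cdc20 was higher by 2.83, the centromere histone Cenpa by 2.02 and Ube2c by 1.71. The checkpoint gene Mad2l1, the condensin gene Smc2, Trip13 and Cenpw, which are outside the list, rose by 2.99, 2.96, 2.98 and 2.92. With the mean of all probe sets of a gene, the rises were 1.83 for Cdc20, 0.67 for Cenpa, 1.53 for Smc2 and 1.92 for Trip13. Of 18 p53 targets, 7 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.85 and an adjusted p = 0.868 with an estimated correlation. Ccng1 rose by 1.27 and Trp53inp1 by 1.45. Without the zinc-treated arrays carrying pancreatic transcripts, 4 p53 targets rose, with a median of 0.27, and Ccng1 rose by 0.62. Under the same omission the cell cycle median was 0.08.

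Of 24 NRF2 targets, 8 rose and 0 fell (12 and 1 adjusted over the list alone; adjusted p = 0.394 with an estimated correlation), with Gstm4 higher by 1.06, Ugdh by 0.63 and Ephx1 by 0.58. Of 21 genes of cholesterol biosynthesis, 4 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.43 and an adjusted p = 0.868 with an estimated correlation. Hmgcs1, which makes HMG-CoA, rose by 1.00. Of 19 fetal liver and tumour markers 3 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.868 with an estimated correlation), with Afp higher by 1.70 (0.77 as the mean of its probe sets) and Tff3 by 1.99. Among genes of other functions, the secreted factor Tafa2 rose by at least 3.41 from a dim level, and Ddias by 3.74.

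Of 26 interferon response genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.23 and an adjusted p = 0.868 with an estimated correlation. The transcription factor Irf7 fell by 1.00 and Ifit2 by 0.78, as they had in untreated mutants, and the immunoproteasome subunit Psmb9 rose by 0.84. The median was -0.39 without the arrays carrying pancreatic transcripts. Of 25 macrophage markers 0 passed over all genes and 10 fell adjusted over the list alone, with a median of -0.50 and an adjusted p = 0.868 with an estimated correlation. Of 17 male-biased liver genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.868 with an estimated correlation). Moxd1 remained lower by 5.43, whereas Ugt2b38 differed by -0.06. The median was -0.33, and -0.52 without the arrays carrying pancreatic transcripts. Alas1, the first enzyme of heme synthesis, fell by 1.47, Gas1 by 1.31 and the adhesion molecule Cadm4 by 1.49.

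By camera at the preset correlation 10 lists were called, 7 up and 3 down, against 0 with an estimated correlation (smallest unadjusted p = 0.0178) and 2 by fry, where simulated data without an effect gave a median of 10 at the preset correlation. With dim genes left out the median was 0.61 for the cell cycle and -0.04 for interferon response genes, whose list was then not called (adjusted p = 0.123). Without 1 array, it was 0.28 for the cell cycle (zinc-treated replicate 1), 0.56 for p53 targets (zinc-treated replicate 2), -0.27 for macrophages (wild type replicate 2), and -0.14 and -0.35 for interferon response genes (wild type replicates 3 and 4). With the mean of all probe sets it was 0.50 for p53 targets. Without the 2 zinc-treated arrays carrying pancreatic transcripts 699 genes were called, 619 of them among the 1386.

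Setting the comparisons side by side asks which changes of the mutant liver were reversed with zinc. Of the 4480 genes changed in Atp7b-/-, 1002 changed the opposite way with zinc, 764 of them raised in the mutant and 238 lowered. Another 3, Cyp39a1, Lpl and Myom2, changed further the same way, all upwards. The largest opposite changes included Ugt2b38, Birc5, Robo1, Stap1, Cfap53, Esco2, Slc35f2 and Ttk. Of the 1002 genes, 717 did not differ from wild type after zinc by the test, 282 still did in the mutant's direction and 3 in the other. A further 871 genes did not pass the test between treated and untreated mutants and still differed from wild type, Ddias and Tafa2 among them. The largest class, 2604 genes (58.1%), passed neither test after zinc, so these tests leave open whether they were reversed. Among the 1002, 76.2% were raised in the mutant, and 62.6% after quantile normalization.

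Both comparisons used the untreated Atp7b-/- arrays, with opposite sign, so some opposition arises by chance. Across genes, which are not independent replicates, the changes correlated at -0.75, against -0.47 in simulated unchanged groups, and their covariance was -0.103 against -0.0106. With the shared arrays split between the comparisons the correlation was -0.63, and 435.5 genes overlapped on average where independent calls would give 54.5. The 1002 genes became 536 without the zinc-treated arrays carrying pancreatic transcripts and 610 without replicate 4 of Atp7b-/-.

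Against wild type, 1156 genes changed the same way with and without zinc, 803 up and 353 down, and 3 changed in opposite directions. The changes correlated at 0.78 across genes, against 0.52 in simulated unchanged groups, with a covariance of 0.112 against 0.0112. With the wild type arrays split, the correlation was 0.66 and 595.3 genes overlapped on average where independent calls would give 81.3. Without the zinc-treated arrays carrying pancreatic transcripts the count was 613. Myom2, a muscle gene on chromosome 8 that is 28 tested genes from Atp7b, rose by 5.83 without zinc and 6.93 with it. Mcph1, 26 genes away, rose by 1.93 and 1.40, and Nek3, 3 genes away, by 1.40 and 1.05. With the mean of all probe sets of a gene, Myom2 rose by 3.01 and 3.81 and Mcph1 by 1.02 and 0.74. Without probe sets prone to cross-hybridise, Myom2 rose by 3.79 in untreated mutants. Myom2 was dim in wild type (3.55), so its rises are lower bounds.

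**Figure D3:**
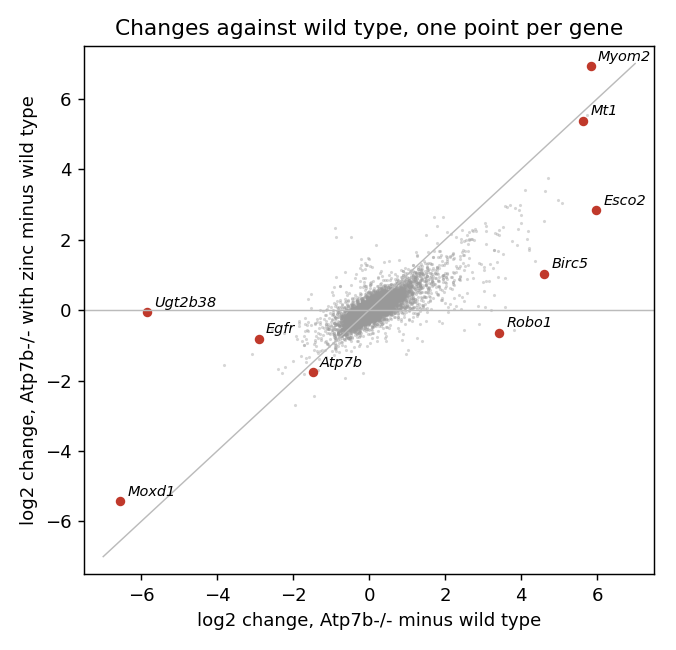
Log2 change of each of 18193 genes against wild type, in untreated Atp7b-/- (horizontal) and in zinc-treated Atp7b-/- (vertical); points on the diagonal changed alike and points on the horizontal line did not differ from wild type with zinc. Moxd1 (-6.56 and -5.43) lies near the diagonal, and Ugt2b38 (-5.84 and -0.06) near the horizontal line.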

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

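The tests of mixed sexes, hepatocyte share, growth hormone signalling and RNA degradation, and that of a larger change in all lists, were chosen only after the result was seen. An array is listed here when its gap to the nearest array of its group, as a share of the range of the group, passed Dixon's 95% critical value. Chance does this in about 1 in 20 groups, or 5%, and here 33 of 453 groups (7.28%) passed. Of the 33, 14 were in replicate 1 of untreated Atp7b-/- and at most 3 in any other array.

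In replicate 1 of untreated Atp7b-/-, the genes set apart, with their gap ratios, were Cyp2c29 (0.898), Dhcr7 (0.834), Gas1 (0.862), Hmgcs1 (0.899), Kmo (0.907), Pmvk (0.858) and Slc31a1 (0.854), all lower than in the other 3 arrays. Ddit4l (0.859), Irf7 (0.858) and Sult1e1 (0.910) were higher. The mean of the NRF2 targets (0.848) and that of interferon response genes (0.957) were also higher, and that of urea cycle and amino acid genes (0.903) was lower. The ratio of its median correlation within the group was 0.933. Other untreated Atp7b-/- arrays stood apart for Cenpa (0.874, lower in replicate 2), Zfp36 (0.931, lower in replicate 3) and Egfr (0.866, lower in replicate 4).

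Among wild type arrays, Anxa5 was higher (0.899) and Igfals lower (0.844) in replicate 1, and Slco1a1 was lower in replicate 2 (0.993). Ctse (0.846) and Hsd17b6 (0.903) were higher and Igf1 (0.908) lower in replicate 4. Replicate 3 had a higher median correlation with its group (0.977). Among zinc-treated arrays, Hsd17b6 was higher (0.988) and Myom2 lower (0.877) in replicate 1, and Mcph1 (0.850), Tek (0.840) and the mean of adipocyte genes (0.844) were higher in replicate 2. Smc2 was lower in replicate 3 (0.848), where the median of all probe sets was higher (0.921). Sc5d was higher (0.875) and the actin 3' to 5' difference smaller (0.859) in replicate 4.

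Probe sets that name no single gene also carried signal. Of 10092 such probe sets, 1335 differed between Atp7b-/- and wild type (578 higher, 757 lower), 299 with zinc against untreated (95 higher, 204 lower), and 259 with zinc against wild type (135 higher, 124 lower), by limma at the same threshold.

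Of the 35 splits of 8 arrays into 4 and 4, the real one alone, 1 of 35, called as many genes in each comparison. That is the smallest share that 35 splits can give, and the 3 comparisons share arrays. The test therefore cannot exclude chance in the grouping. In fits of those 8 arrays the real count was 3884 for Atp7b-/- against wild type, with 5 as the highest of the other splits. It was 1028 against 1 for zinc against untreated, and 1268 against 2 for zinc against wild type.

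Of 17 male-biased liver genes, Ugt2b38, Moxd1 and Slco1a1 among them, 13 fell in Atp7b-/- and 4 rose with zinc, where the interval of the median over genes, -0.11 to 1.13, includes 0. Mixed sexes were argued against, since the Y-linked mean was 0.23 log2 units higher in the mutant than in wild type (-0.14 to 0.60 at 2 SD between arrays). A lower share of hepatocyte RNA was too, since the hepatocyte list lay 0.72 above the male-biased list (0.49 to 1.51 over genes). Its own median was -0.01, although 4 of its 23 genes fell and 0 rose. Weaker growth hormone signalling stays open: the growth hormone and IGF list, which shares 0 genes with the male-biased list, had a median of -0.19 in the mutant (-0.58 to -0.07 over genes) and 0.18 with zinc (0.03 to 0.43), but was called in 13 of 22 alternative settings for the mutant and not with an estimated correlation (adjusted p = 0.541). The growth hormone and IGF list mixes receptors, binding proteins, signalling genes and targets, whatever the direction in which growth hormone moves each. Its median therefore does not measure the strength of signalling and cannot decide this. By array, the mean of this list in untreated replicate 4 (-0.04) lay within the wild type range of -0.12 to 0.09. Zinc-treated replicate 4 had the highest mean of this list in its group (0.35) and the lowest of the male-biased list (-1.15).

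Some genes near Atp7b differed from wild type in both mutant groups, Myom2, Mcph1 and Nek3 among them. Of the 100 tested neighbours of Atp7b, 12 were called the same way in both comparisons, against a 95th percentile of 11 and a highest value of 17 in 15847 windows elsewhere. A segment of donor chromosome carried along with the disrupted gene could explain this, by a narrow margin: for changes of at least 2-fold the count was 3, equal to the 95th percentile. An effect of Atp7b loss on its neighbours cannot be told apart from such a segment, because 0 of the groups could hold the segment without the disruption.

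Replicate 1 of untreated Atp7b-/- had the lowest median correlation within its group. RNA degradation was argued against, as its 3' to 5' difference of control probe sets was 0.79, within the 0.54 to 0.88 of the other 11 arrays. The 0.88 was of another untreated Atp7b-/- array, and replicate 1 had the smallest difference of its group. This covers replicate 1 within its group only, since every untreated Atp7b-/- array had a larger difference than any array of the other groups. RNA of pancreas or fat was argued against too. The acinar mean was 0.06 above the median array, and the adipocyte mean (6.48) lay below the lowest other array (6.54). The largest excess of 5 marker lists over the highest other array was -0.036. A zinc-treated array carrying pancreatic transcripts set that bar for acinar and adipocyte genes. Other cell types stay open, as lymphocyte markers were higher than in the other 3 mutant arrays (-0.03 against -0.37 to -0.25). Cholangiocyte markers, which were not among the 5 lists, were highest in this array (0.47 above wild type). For a larger change of the same kind in all lists, the 16 lists called without this array were used. It lay beyond the other 3 mutant arrays in 5: p53 targets (2.00 against 1.54 to 1.70), cell cycle genes, fetal markers, NRF2 targets and male-biased genes (-1.84 against -1.38 to -1.16). In 8, macrophage and interferon genes among them, it lay short of the others by more than their range. Choosing lists without this array favours those where it differs. Interferon genes, for instance, were not called with all arrays (adjusted p = 0.225 by camera at the preset correlation). The test therefore does not decide whether the change was larger in all lists. A larger change in all lists or in part of them stays open, as do other differences between animals, which were not tested. The correlation across genes of the deviation of this array with the change in the other 3 was 0.0360, or 0.0850 with different mutant arrays on the 2 sides. The latter lies within the -0.182 to 0.196 of the other 3 and decides nothing.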

How the results depend on the processing

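The settings that leave out the arrays with pancreatic transcripts, alone or with replicate 1 of untreated Atp7b-/-, were chosen after seeing the data. Counts are given in the order Atp7b-/- against wild type, zinc against untreated, zinc against wild type, changed the opposite way with zinc, and changed the same way against wild type.

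Testing every probe set gave 8475, 2013, 2158, 1686 and 1802 probe sets, as more units were tested. A change of at least 1 log2 unit, a stricter threshold, left 655, 205, 229, 181 and 201 genes. Array weights gave 1861 genes for zinc against untreated, and the cause was not tested. With fewer arrays, the zinc arrays with pancreatic transcripts left out gave 614 and 699 for the zinc comparisons, 536 opposite and 613 the same way. With replicate 1 of untreated Atp7b-/- left out too, the counts were 598, 881, 516 and 741. Of the 614 and 699 genes, 526 and 619 were also called with all arrays.

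Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons, and fry called 7 for zinc against untreated and 2 for zinc against wild type. The estimates were 0.49 for p53 targets, 0.37 for the cell cycle, 0.42 for male-biased genes and 0.55 for macrophages, against the preset 0.01. A higher correlation makes camera stricter by construction. For growth hormone and IGF genes the estimate was -0.02, so this does not cover every list. Why fry called fewer lists was not tested.

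Leaving out 1 array at a time gave 3292 to 4495, 689 to 1158, 932 to 1639, 610 to 954 and 808 to 1319 genes. The counts of 689 and 610 were without replicate 4 of untreated Atp7b-/-. Lists called ranged from 8 to 16, 14 to 18 and 9 to 12, and the change of Atp7b from -1.53 to -1.42.

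Of 9929 values of named genes under the alternatives, 6623 belonged to changes called in the main fit. Of the 9929, 9298 kept their side of the threshold, 479 lost a call, 149 gained one and 3 called changes reversed. The 9298 include changes not called in either fit, whose direction could differ. Those 3 came without probe sets prone to cross-hybridise, which replaced the probe set of the gene: Hamp2 at -0.13 in Atp7b-/- and 0.068 with zinc against untreated, and Cox17 at 0.039 with zinc against untreated.

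With the replicate number as a block, 4449, 1171, 1353, 996 and 1134 genes were called. Same-numbered pairs of arrays correlated from -0.130 to 0.237 and other pairs from -0.224 to 0.266. Since 6 of 12 arrays correlated best with their own number, some pairing by number stays open. The main fit did not use the numbers. Not run were the other offset before the log, since the values were already log2, and a sex covariate, since all arrays had a male pattern.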

Other observations

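Of 18 genes of lipid uptake and storage, 3 rose and 2 fell in Atp7b-/- against wild type (4 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.769). Lpl, which releases fatty acids from lipoproteins, rose by 1.95 and the fatty acid transporter Cd36 by 1.95. Of the lipid droplet coat genes, Plin3 rose by 0.64 and Plin2 fell by 0.61.

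Of 17 genes of bile acid transport, 5 rose and 7 fell, by either count, and the list was not called (adjusted p = 0.681). The bile salt importer Slc10a1 fell by 1.31 and the bile salt exporter Abcb11 by 0.56, while the phospholipid exporter Abcb4 rose by 0.53. With zinc against untreated, Abcb11 rose by 0.66. Slc10a1 rose by 0.82 (0.53 without replicate 1 of Atp7b-/-), a call lost in 11 of the settings tried.

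Of 24 genes of the unfolded protein and amino acid stress responses, 2 rose and 8 fell (2 and 10 adjusted over the list alone), and the list was not called (adjusted p = 0.0513). The asparagine synthetase gene Asns rose by 3.06 in Atp7b-/- and was 2.48 above wild type with zinc, whereas Ddit3, another gene of the amino acid stress response, fell by 1.24 and 1.15. Of 25 genes of zinc transport, 5 rose and 2 fell, by either count, and the list was not called (adjusted p = 0.464). The zinc transporter genes Slc39a11 and Slc39a3 rose by 0.65 and 0.49 in Atp7b-/-, Slc39a3 by 0.17 as the mean of its probe sets. Slc39a11 fell by 0.57 with zinc against untreated.

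Of 18 female-biased liver genes, 4 rose and 0 fell in Atp7b-/- (5 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.0513). The estrogen sulfotransferase Sult1e1 rose by 3.57 in Atp7b-/-, from a dim level (4.24) and so as a lower bound, and fell by 2.67 with zinc, and Cyp17a1 fell by 1.34 with zinc against untreated.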
